A study of Mus musculus with 4 samples.

How the data were processed

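RNA from 4 samples of OP9 cells, a mouse bone marrow stromal cell line, was measured on 1-colour Agilent mouse arrays, 1 array per sample. The 2 Control samples carried a retroviral vector alone and the 2 Wnt3A samples carried the same vector with the Wnt3A gene. Per the labels, the RNA was amplified by a global PCR method before hybridisation. The labels call the samples of a group replicates and do not say whether they came from separate cultures, so the p-values measure the spread between these samples. The number of arrays limits the precision of every value.

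Both a table of all samples and 1 scanner output file per sample were deposited. The deposited table holds a linear intensity for each of 43379 non-control spots, and every column has a median of 1. How the authors reached that scale beyond the use of Agilent Feature Extraction is not stated. Per the file headers, the scanner files hold intensity values from Feature Extraction 10.5.1.1, both as raw spot means with local background and after background subtraction and detrending within the array, with no scaling between arrays. The scanner files also hold flags of other kinds, deposited as 0 or 1 per spot for signal well above background, saturation and uneven spots.

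The plan fixed before the data were examined named the scanner values as the main source and the table as an alternative. The table was made the main source only after the values of both had been compared. All 4 table columns were closest in rank to 1 scanner file, that of Control replicate 2, which files of unequal quality would also give, and arrays of 1 group were more alike than arrays of different groups in the table but not in the scanner files. The second of these reasons bears on the comparison itself, so the choice favoured the source in which the groups differ, and the counts from the scanner values as planned are given beside the main counts. The table has no flags, so saturation could not be checked, and its detection floor was estimated. The floor of each array was 4.94 times the 1st percentile of its column, the median of the factors of the 4 scanner files (4.85 to 4.99), which may hold other arrays than the table, and this was also chosen after the values were seen. Each factor was the lowest signal flagged well above background in a scanner file, divided by the 1st percentile of that file. It rests on the dimmest flagged spot, so the floor is a lenient one. Floors were 0.0702 and 0.0631 in the Control arrays and 0.0533 and 0.0729 in the Wnt3A arrays.

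Values were taken to log2 and the 75th percentile of each array was subtracted. The spots of a probe were averaged, giving 41174 probes. Probes above the floor on both arrays of at least 1 group were kept. Probes were named from the reference table through the transcript accession in the array annotation for 24375 probes and through the symbol for 8727 probes, and 8072 kept the name in the file. Probe positions are on mouse genome build mm8 as the array annotation gives them. A genome sequence was not used here, so what lies at a position beyond the gene name is not given. Each gene was represented by its kept probe with the highest mean over the 4 arrays.

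The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings, a two-sided test), and p-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 2.29. A fold change against a group with no array above the floor was computed against the floor and is given as a lower bound, which is 2 times smaller with a floor 2 times as high. It is a lower bound only if the true limit of detection lies no higher than this lenient floor, which was not tested. No exact test of 2 against 2 arrays can give a two-sided p below 0.333.

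The same fit was tested on simulated data in 5 runs of 33709 probes. The noise of each probe was drawn with its eBayes variance. This differs less between probes than the measured variance, so the recovery in all simulations may be overstated. The fit recovered 0% of changes of 1 (log2), 1.6% of changes of 2, 75.2% of changes of 4 and 93.6% of changes of 6. It called 4.2 unchanged probes per run. Sizes between 2 and 4 were not simulated. In 20 simulated runs, camera called a list shifted by 2 (log2) in 100% of runs with the preset correlation and in 0% with an estimated one. Genes were drawn independently of each other, so these runs do not cover lists of correlated genes.

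Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, two-sided and adjusted over the lists, with at least 5 measured members required. Camera with an estimated correlation and fry were the alternatives. The 32 lists, with 814 entries, were written before the data were examined. They covered Wnt target genes, Wnt ligands and R-spondins, Wnt receptors and transducers, secreted Wnt antagonists, adipocyte genes, osteoblast genes, chondrocyte genes, proteoglycans and hyaluronan, collagens and matrix glycoproteins, matrix proteases and inhibitors, and hematopoietic niche factors. They also covered Notch signalling, BMP and TGF-beta signalling, growth factors and IGF binding proteins, cell cycle, interferon response, inflammatory cytokines and NF-kB, endoplasmic reticulum stress, p53 targets, glycolysis and hypoxia, and cholesterol synthesis. Smooth muscle and contractile genes, mesenchymal stromal markers, cadherins and integrins, guidance genes (ephrins and semaphorins) and housekeeping genes completed the 26 pathway and control lists. The remaining 6 lists marked other cell types (macrophage and myeloid, lymphoid and erythroid progenitor, endothelial, epithelial, neural and skeletal muscle). The median of each list was the same with genes bounded by the floor set at their bound.

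Single genes were named by a rule fixed before the data were examined. Wnt3a, Axin2, Lef1, Nkd1, Ctnnb1, Pparg, Cebpa, Runx2, Dcn, Cxcl12 and Kitl were always named. The 10 largest rises and the 10 largest falls among genes past the threshold with signal above the floor in both groups followed, leaving out accessions, clone names and predicted loci. Up to 5 genes per direction with no array of the lower group above the floor were named by their bounded fold. Each list gave up to 4 members past the threshold with the largest change, or, where none passed, the 2 with the smallest unadjusted p. Genes outside this rule are named as chosen after their values were seen.

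Alternatives fixed in advance were other scalings, normexp background correction with an offset of 50, no filter, a stricter filter, dim values set to the floor, eBayes with trend and robust settings, the replicate number as a block, the mean of a gene's probes, other thresholds, and leaving out each array. Added after the data were seen were the table without further scaling, quantile normalization of the table, a floor 2 times as high, and the planned scanner fit as the alternative. The normexp settings need raw signals, so these and the planned quantile setting were run on the scanner values for counts of genes and lists and for the similarity of arrays. A slide block was not run. All 4 scanner files name 1 slide, and the slides behind the table are not known.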

Results

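Gene expression was measured in OP9 mouse stromal cells that carried a retroviral vector alone (Control, 2 arrays) or the vector with the Wnt3A gene (Wnt3A, 2 arrays). OP9 cells are used to support blood progenitors in culture, and the comparison asked how Wnt3A changed the genes of the supporting cells. In the table of intensities the median of each array was 1, and 81.8% and 82.0% of spots in the Control arrays and 83.7% and 80.7% in the Wnt3A arrays lay above the estimated floor. In the scanner files, 41.8% and 84.9% of Control spots and 85.7% and 71.6% of Wnt3A spots were well above background. The median intensity there was 7.32 and 178 in the Control files and 147 and 95.0 in the Wnt3A files. The file of Control replicate 1 was thus faint, and every comparison on the scanner values includes it.

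The single Wnt3a probe was read first. Its intensity in the table was 0.0151 and 0.0134 in the Control arrays and 0.0112 and 0.123 in the Wnt3A arrays, so it was above the floor only in Wnt3A replicate 2, and the gene did not enter the test. With a floor 2 times as high it was above it on 0 arrays. In the scanner files it was well above background on 2 arrays, Control replicate 2 and Wnt3A replicate 1. The probe starts at position 2599 of its transcript, and the labels do not say whether the vector's insert reaches that far, so the probe does not show whether the inserted gene was expressed.

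Across the kept probes in the table, Pearson's r between arrays was 0.930 within Control and 0.935 within Wnt3A, and 0.876 to 0.885 between the groups. Probes were kept by group, which favours a gap between the groups. The lowest r within groups minus the highest between was 0.0453. It was 0.0207 with no filter and 0.0295 with probes above the floor on all 4 arrays. Probes are not independent replicates, and no test was made on these values. The median standard deviation within groups was 0.41 on the log2 scale and 0.27 for probes brighter than the 75th percentile. In the scanner files r was 0.668 within Control, 0.680 within Wnt3A and 0.585 to 0.799 between the groups, so the arrays did not fall into the groups there. The median percentile of collagens and matrix glycoproteins within an array was 82.4 to 85.6 in the table and 52.9 to 69.2 in the scanner files. For macrophage and myeloid markers it was 49.3 to 51.1 in the table and 76.6 to 95.3 in the scanner files.

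**Figure D1:**
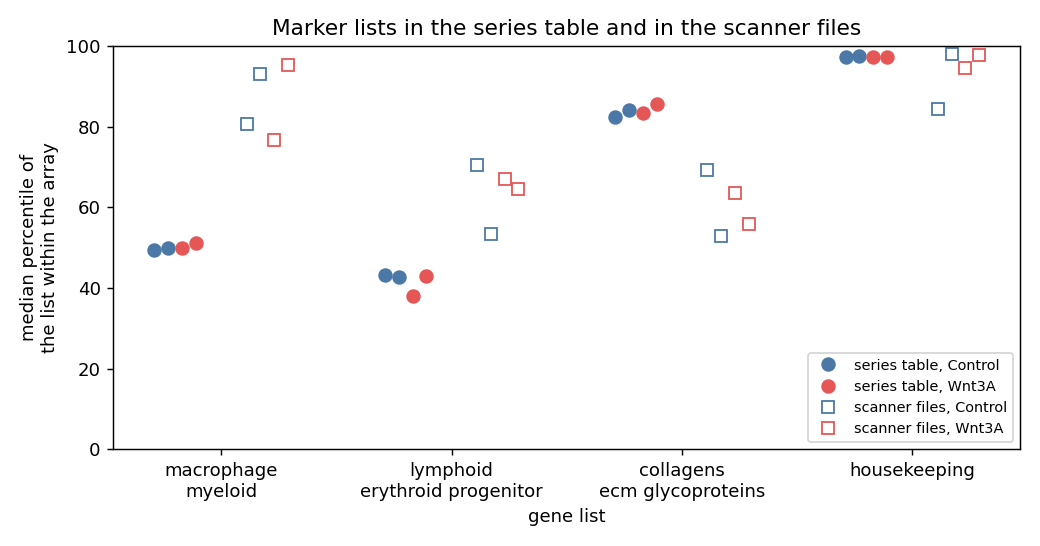
Median percentile within each array of macrophage and myeloid markers, lymphoid and erythroid progenitor markers, collagens and matrix glycoproteins, and housekeeping genes, with filled circles for the table and open squares for the scanner files. Myeloid markers lay at 49.3 to 51.1 in the table and at 76.6 to 95.3 in the scanner files.

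Of 22859 genes tested in the table, 92 rose and 55 fell in the Wnt3A arrays at an adjusted p under 0.05 in limma, which corresponded to 143 and 86 of 33709 probes. The log2 size of the changes ran from 3.25 to 12.25 for the rises and from 3.10 to 11.67 for the falls, and the smallest adjusted p was 0.0226. These sizes were taken without the floor. Against the floor, the largest rise (Tnn) was at least 10.17 and the largest fall (Lcn2) at least 9.50. Of the genes that rose, 50 had no Control array above the floor, and of those that fell, 23 had no Wnt3A array above it. At an unadjusted p under 0.05, 1443 genes were higher and 1450 lower. The values of both groups did not overlap in 45.2% of genes, where chance gives 33.3%, but the filter by group favours genes without overlap. Of 39 called genes with more than 1 kept probe, 37 had all probes in the same direction. The scanner values, tested in limma as planned, gave 0 genes that rose and 2 that fell, with 480 at an unadjusted p under 0.05. Those 2 were transcripts without a gene symbol, chosen here after their values were seen, of which 1 fell by 7.62 (log2, adjusted p 0.00257) and the other fell by 6.69 (0.0375). In the table both were higher, the latter by 0.34 and the former by 1.004, and neither passed there. Of the 75 genes called in the table that the scanner values also measured, 32 changed in the same direction there and 43 in the opposite one. How far this rests on the faint scanner file of Control replicate 1 was not tested.

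No gene called in the table stayed past the threshold when any 1 of the 4 arrays was left out. Without Control replicate 1 or Control replicate 2, limma called 0 genes, with 2765 and 2822 at an unadjusted p under 0.05. Without Wnt3A replicate 1 or Wnt3A replicate 2 it also called 0, with 2421 and 2281. The direction was kept by all 147 called genes in 3 of these fits and by 146 without Control replicate 2. Genes called for large changes on these same arrays would nearly all keep their direction, so these counts do not measure stability. In simulated data a fit without 1 Control array recovered 0% of changes of 2 (log2), 2% of changes of 4 and 68.8% of changes of 6. Of the 147 called changes, taken without the floor, 23 were below 4, 74 lay from 4 to 6 and 50 were 6 or more. A fit without a Wnt3A array was not simulated. With no filter on dim probes 20 genes rose and 15 fell, and with only probes above the floor on all 4 arrays 21 rose and 13 fell. The latter setting measured only 70 of the 147 called genes.

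The largest rises among genes with no Control array above the floor were those of Tnn, Panx3, Wif1, Itga11 and Sfrp2. Each lower bound given as a fold rests on the estimated floor and is 2 times smaller with a floor 2 times as high, which for Tnn gives 575-fold. Tnn was at least 1150-fold higher (chromosome 1, 161922408 to 161922466 on mm8, adjusted p 0.0226). Panx3 was at least 502-fold higher (adjusted p 0.0293), Wif1 at least 268-fold (0.0226), Itga11 at least 256-fold (0.0279) and Sfrp2 at least 230-fold (0.0279). Tnn, like Dpt and Fmod, lies on chromosome 1, whose genes as a group had a median change 0.22 above that of the other chromosomes. Among genes with signal in both groups, Postn rose by 9.35 ± 0.43 (log2, SE, 2 arrays per group), from a mean of -6.12 to 3.23, with an adjusted p of 0.0226 (chromosome 3, 54478490 to 54478549). By the mean of its probes, of which 1 of 2 passed, the change of Postn was 6.76 (0.0247). Only 1 Control array was above the floor for Postn, Itm2a (a log2 change of 8.62) and Dpt (8.40). The next were Pdzrn3 (7.75), Fmod (7.39), Tnc (7.22), Fgfr2 (7.21), Nkd2 (6.47), Hoxb9 (6.29) and Plagl1 (6.23), each above the floor on all 4 arrays, with adjusted p from 0.0226 to 0.0398. By the mean of a gene's probes the changes were 5.64 for Fgfr2 (2 of 3 probes passed), 4.68 for Plagl1 (1 of 2), 5.61 for Hoxb9 (2 of 2), 6.26 for Nkd2 (1 of 2) and 7.16 for Tnc (2 of 3), and all 5 genes passed.

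Lcn2 showed the largest fall. It was at least 722-fold lower in the Wnt3A arrays (chromosome 2, 32207526 to 32207770, adjusted p 0.0226), where no array was above the floor. Rian was at least 74.3-fold lower, Mme at least 45.6-fold, Ces1f at least 44.8-fold and Id4 at least 37.2-fold, with adjusted p from 0.0226 to 0.0338. For Rian and Mme, 1 of 2 probes passed. Among genes with signal in both groups, Angpt1 fell by 8.32 ± 0.32 (log2, SE), from 3.28 to -5.04, with an adjusted p of 0.0226 (chromosome 15, 42257097 to 42257156). The log2 changes of the next were -7.67 for Meg3, -7.51 for Efemp1, -7.40 for Prl2c5, -6.64 for Ccl9, -5.85 for Cygb, -5.74 for Gstt1, -5.65 for Mgst2, -5.63 for Aldh3a1 and -5.19 for Nid1, with adjusted p from 0.0226 to 0.0493. For Meg3, 2 of 4 probes passed, and its change was -4.01 with the mean of its probes. Gstt1 passed in 4 of 14 alternatives in the table, and its call was lost under the other 3 scalings (0.0501 to 0.0555), with no filter (0.0767) and with probes above the floor on all 4 arrays (0.0642). Prl2c5 has close paralogs, and whether its probe tells them apart is not known.

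**Figure D2:**
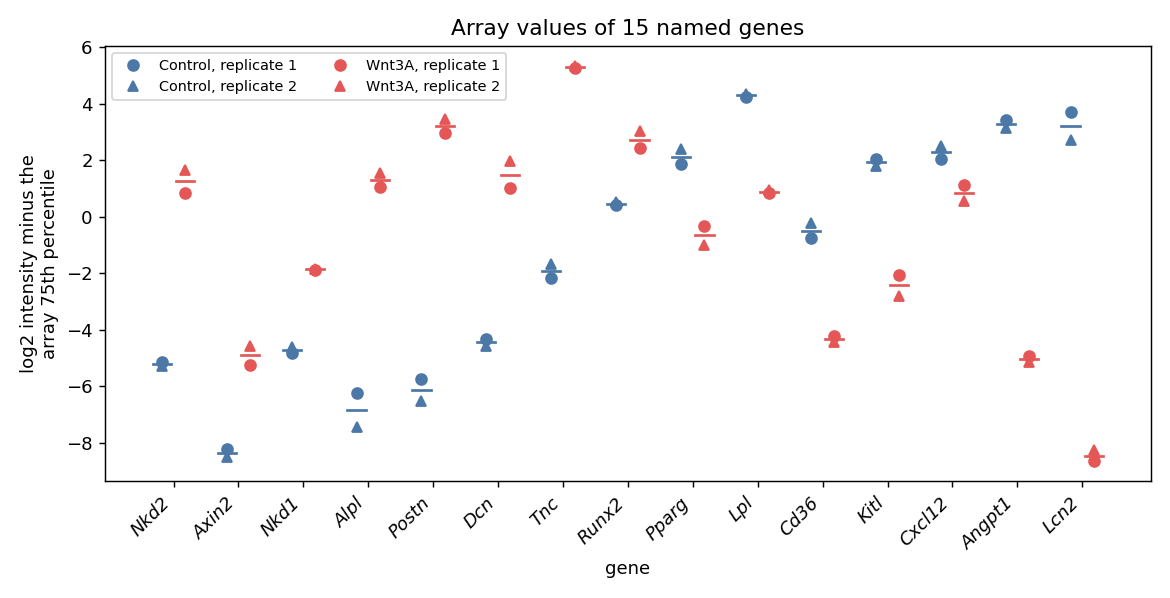
Array values of 15 named genes, as log2 intensity minus the array's 75th percentile, with circles for replicate 1, triangles for replicate 2 and lines for group means. Kitl fell from a mean of 1.93 to -2.43 and Nkd2 rose from -5.21 to 1.26, while Axin2, Nkd1, Runx2, Pparg and Cxcl12 did not pass the threshold.

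Of the 32 lists, 3 were higher and 4 lower in the Wnt3A arrays in camera with the preset correlation. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.385. Fry, which asks only whether a list's genes move one way on balance, passed 6 lists. Within the table, the calls of 5 lists (Wnt targets, adipocyte, osteoblast, proteoglycan and niche genes) held in 15 of 16 alternatives, all but the estimated correlation. The scanner values as planned gave 0 lists in either direction, and so did the 2 fits with quantile normalization. With normexp they gave 3 higher lists and 0 lower, cell cycle (0.0189), endoplasmic reticulum stress (0.0352) and glycolysis and hypoxia (0.0189), the last of which was called lower in the table.

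Wnt target genes were higher, with a median log2 change of 1.01 over 29 genes, 21 of them higher and 8 lower (camera adjusted p 7.05e-07, fry 0.00564). The list had 2 genes that rose and 0 that fell over all genes tested, against 12 and 1 adjusted over the list alone. The median was 0.67 with only probes above the floor on all 4 arrays. The 2 genes were Wif1 and Nkd2. Nkd2 rose by 6.47 ± 0.41 (SE, adjusted p 0.0293). Axin2 was at least 2.45-fold higher with no Control array above the floor (1.23-fold with a floor 2 times as high), but its adjusted p of 0.0645 did not pass. It passed with a floor 2 times as high (0.0498) and with the mean of a gene's probes, and its adjusted p ran from 0.0477 to 0.291 over the 13 alternatives in the table. Nkd1 also missed the threshold, with a change of 2.86 ± 0.30 and an adjusted p of 0.0581, as did Lef1 (1.56, 0.271) and Ctnnb1 (0.67, 0.478). Nkd1 passed with a floor 2 times as high (0.0438, range 0.0438 to 0.228). By the mean of a gene's probes the changes were 1.73 for Nkd1, 2.85 for Lef1 and 0.14 for Ctnnb1, and none of these passed. Secreted Wnt antagonists did not pass as a list (median 0.03, 10 genes, 0.3005) although Sfrp2 rose. Wif1 had been placed among the Wnt target genes and was not counted in that list. Wnt ligands and R-spondins had a median of 0.10 (20 genes, 0.117), and Rspo3 was at least 36.5-fold higher. That list passed with the mean of a gene's probes (0.0154, within a range of 0.0154 to 0.609 over 16 alternatives in the table). Wnt receptors and transducers had a median of 0.20 over 31 genes (0.314), and none of them passed. The members with the smallest p were Fzd2 (1.52) and Dvl3 (1.49).

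Osteoblast genes were higher, with a median of 1.12 over 20 genes, 16 higher and 4 lower (camera adjusted p 3.66e-06, fry 0.0188). Over all genes tested 6 rose and 1 fell, and adjusted over the list alone 9 rose and 2 fell. Alpl was at least 181-fold higher and Ibsp at least 79.2-fold, and Pth1r rose by 5.08 ± 0.34 (SE, adjusted p 0.0313). Runx2 changed by 2.26 ± 0.36, or by 1.06 with the mean of its 4 probes, and did not pass in either case (0.116 and 0.276). Sp7, which rose by 4.57, and Dlx3, at least 5.96-fold lower with no Wnt3A array above the floor, were also past the threshold. Both were chosen after their values were seen. Chondrocyte genes did not differ as a list (median -0.14, 18 genes, 0.831). Col11a1 (3.23, 0.0556) and Sox5 (-2.73, 0.121) had the smallest p among them. For Col11a1, 1 of 2 probes passed, and the gene passed with the mean of both (5.66, 0.0187), with a floor 2 times as high (0.0419) and with trend and robust settings (0.0264), 3 of 14 alternatives in the table (0.0187 to 0.221).

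Proteoglycan and hyaluronan genes were higher, with a median of 1.01 over 24 genes, 14 higher and 10 lower (camera adjusted p 0.00286, fry 0.0188). Over all genes tested 3 rose and 0 fell, and adjusted over the list alone 7 rose and 2 fell. The median was 0.53 without Control replicate 2 and 0.64 with the mean of a gene's probes, and the list passed in both. Dcn rose by 5.94 ± 0.45 (SE, adjusted p 0.0348). Fmod rose by 7.39 and Omd by 4.10, though Omd passed in only 5 of 14 alternatives in the table and was lost, among other settings, with quantile normalization (0.0555). Collagens and matrix glycoproteins went both ways. Over 47 genes, 25 were higher and 22 lower, the median was 0.04 and the adjusted p 0.978, with camera's direction opposite in sign to the median. Over all genes tested Tnc and Nid2 rose, by 7.22 and 3.76, and Efemp1 and Nid1 fell, as did Tnxb (-3.42), which was chosen after its value was seen. Adjusted over the list alone 11 rose and 13 fell. Matrix proteases and inhibitors had a median of 0.12 over 30 genes (0.265), and Adamts9 rose by 6.09. For Adamts9, 1 of 3 probes passed, and its change was 3.59 with the mean of its probes. That list passed in fry (0.0188) and with the mean of a gene's probes (0.0338), within a range of 0.0188 to 0.742 over 16 alternatives in the table.

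Adipocyte genes were lower, with a median of -1.20 over 34 genes, 4 higher and 30 lower (camera adjusted p 1.78e-09, fry 0.0188). None of them rose, 3 fell over all genes tested, and 13 fell adjusted over the list alone. Lpl fell by 3.42 ± 0.30 (SE, adjusted p 0.0441), from 4.31 to 0.89, and passed in 7 of 14 alternatives in the table. Plin4 fell by 4.04 (0.0338) and Cd36 fell by 3.84 (0.0459). For Cd36, 1 of 2 probes passed, its change was -2.21 with the mean of both probes (0.0970), and it passed in 5 of 14 alternatives in the table. Pparg (-2.79 ± 0.42, adjusted p 0.104) and Cebpa (-2.61 ± 0.53, 0.167) did not pass.

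Hematopoietic niche factors were lower, with a median of -0.38 over 26 genes, 6 higher and 20 lower (camera adjusted p 0.00213, fry 0.0188). Angpt1 and Kitl were the 2 that fell over all genes tested, where 0 rose, and adjusted over the list alone 1 rose and 4 fell. The median was -0.60 with the mean of a gene's probes. Kitl fell by 4.36 ± 0.40 (SE, adjusted p 0.0452) by its brightest probe, and 1 of its 2 probes passed. With the mean of both probes its change was -4.80 and its adjusted p 0.0563, within a range of 0.0242 to 0.194 over the 14 alternatives in the table. Cxcl12 changed by -1.44 ± 0.39 and did not pass (0.250).

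Inflammatory cytokines and NF-kB genes were called lower (camera adjusted p 0.0136), with a median of -0.19 over 27 genes, 11 higher and 16 lower, and fry did not pass them (0.137). Over all genes tested 0 rose and 2 fell, Lcn2 and Ccl9, and adjusted over the list alone 0 rose and 5 fell. The call was lost without Control replicate 1 (0.294), without Wnt3A replicate 2 (0.130) and with no filter (0.0792), within a range of 0.00018 to 0.609 over 16 alternatives in the table. The size of the median depended on single arrays, at -0.70 without Control replicate 2 and -0.41 without Wnt3A replicate 1, and it was -0.12 with no filter. Glycolysis and hypoxia genes were also called lower (0.0361), with a median of -0.38 over 25 genes, 7 higher and 18 lower, though no member passed over all genes or adjusted over the list alone. That call was lost, among other settings, in fry (0.360), with quantile normalization of the table (0.101), with no filter (0.0792) and with probes above the floor on all 4 arrays (0.0513). It was also lost without Control replicate 1 (0.430), Wnt3A replicate 1 (0.142) or Wnt3A replicate 2 (0.0583), and it held in 7 of 16 alternatives in the table (0.00115 to 0.689). Its members with the smallest p were Adm (-3.73, above the floor on 1 Wnt3A array) and Pfkl (from a mean of 4.33 to 3.33).

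**Figure D3:**
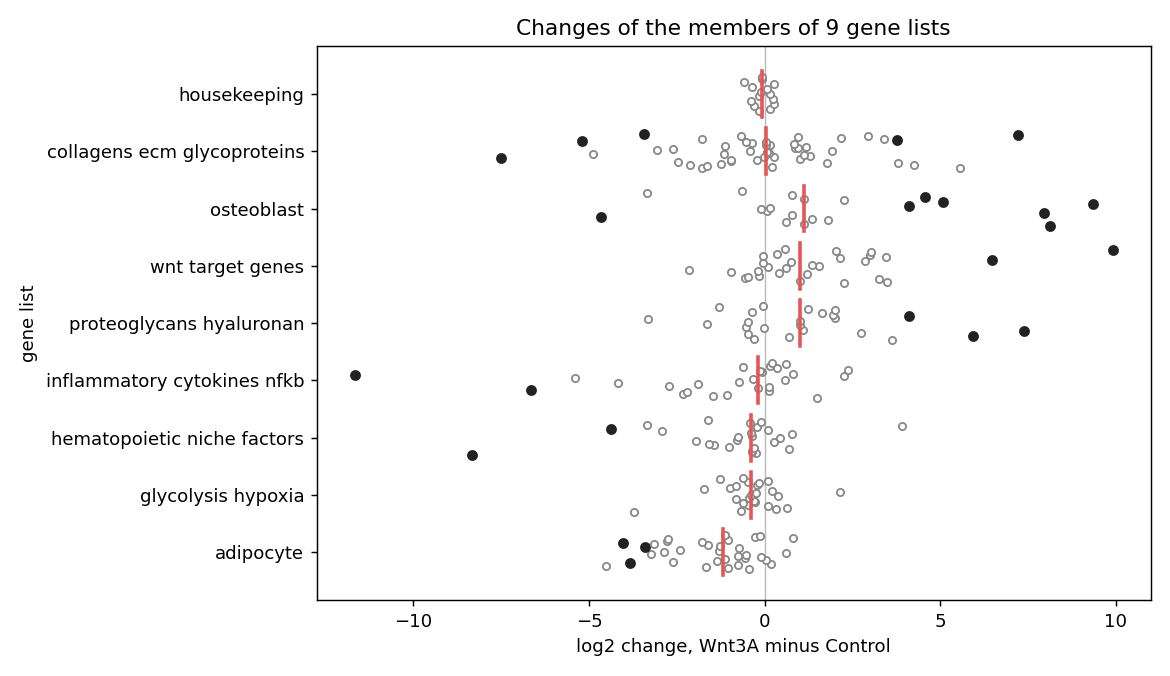
Log2 change (Wnt3A minus Control) of each measured member of the 7 called lists, the collagens and the housekeeping genes, filled where past the threshold, with a red line at the median. The medians were 1.01 for Wnt target genes, 1.12 for osteoblast genes and -1.20 for adipocyte genes.

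The remaining pathway lists did not pass in camera, and the ranges given are over 16 alternatives in the table. Cadherins and integrins had a median of 0.17 over 26 genes (adjusted p 0.117), with Itga11 and Ncam1 (3.91) past the threshold, and the list passed with the mean of a gene's probes (0.0287, range 0.0287 to 0.609). Mesenchymal stromal markers had a median of -0.50 over 19 genes (0.117) with Nt5e at least 53.1-fold higher, and the list passed with only probes above the floor on all 4 arrays (0.0189, range 0.0189 to 0.609). Interferon response genes had a median of -0.36 over 26 genes (0.161) and passed without Control replicate 2 (0.0267, range 0.0267 to 0.609), with Psmb8 (-3.48, 0.0594) and Ifit2 (1.74) the members with the smallest p. Psmb8 passed in 3 of 14 alternatives, among them the mean of its probes (-3.45, 0.0376, range 0.0310 to 0.209). Notch signalling had a median of -0.21 over 22 genes (0.831), and Lfng rose by 4.55. For Lfng, 1 of 2 probes passed, and the call was lost with the mean of both (4.39, 0.0570) and with quantile normalization (0.0516), within a range of 0.0309 to 0.192. BMP and TGF-beta signalling had a median of -0.05 and a mean of 0.09 over 31 genes (0.893), and Id4 fell. Guidance genes had a median of 0.15 over 35 genes (0.314), with 0 past the threshold over all genes and 8 higher and 2 lower adjusted over the list alone, while Robo2 (3.34, 0.0521) and Plxnd1 (-2.52) had the smallest p. For Robo2, 2 of 5 probes passed, and the gene passed with the mean of its probes (4.07, 0.0271), with a floor 2 times as high (0.0389) and with trend and robust settings (0.0296), 3 of 14 alternatives. Plxnd1 passed with trend and robust settings (0.0334, range 0.0334 to 0.259).

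Growth factors and IGF binding proteins had a median of 0.01 over 23 genes (0.792), which was negative under the other scalings of the table, with Igfbp5 (4.24, 0.103) and Igfbp3 (1.73) the members with the smallest p. For Igfbp3, 1 of 2 probes passed, and the gene passed with the mean of both (3.96, 0.0368, range 0.0368 to 0.463). Adjusted over the list alone, 1 member of this list passed (higher), and so did 4 higher Wnt ligands and R-spondins, 1 higher secreted Wnt antagonist, and 4 higher and 1 lower cadherins and integrins. The counts were 1 higher and 1 lower for each of mesenchymal markers, chondrocyte genes and Notch signalling, 1 higher and 2 lower for interferon response, 2 higher and 1 lower for matrix proteases, and 4 higher and 3 lower for BMP and TGF-beta signalling. In the lists that follow, 0 members passed either way.

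The median was 0.01 for cell cycle genes (37 genes, 0.831), with Mybl2 at 1.81 and Cdt1 at -1.39. It was 0.27 for endoplasmic reticulum stress (18 genes, 0.3005), with Herpud1 at 1.75 and Dnajb9 at -0.69. It was 0.16 for p53 targets (17 genes, 0.277), with Plk2 at 1.07 and Eda2r at 0.85. It was -0.27 for cholesterol synthesis (23 genes, 0.3005), with Msmo1 at -1.26 and Idi1 at -0.98. It was 0.20 for smooth muscle and contractile genes (17 genes, 0.360), with Myl9 at 1.57 and Smtn at -0.89. Housekeeping genes had a median of -0.08 (15 genes, 0.831), which was 0.04 with quantile normalization of the table, and Sdha (-0.37) and Tfrc (-0.57) had the smallest p.

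No list of another cell type passed. Macrophage and myeloid markers had a median of -0.01 (23 genes, 0.831), with Cd68 at -1.38 and C1qc below the floor in the Wnt3A arrays. Lymphoid and erythroid progenitor markers had a median of -0.23 (20 genes, 0.443), with Il7r at -0.75 and Ms4a1 at -0.50. Endothelial markers had a median of -0.36 (12 genes, 0.621), with Vwf at 0.82 and Sox18 at -0.68, and epithelial markers one of -0.02 (13 genes, 0.831), with Cldn7 at 1.69 and Cdh1 at -1.23. Neural markers had a median of 0.04 and a mean of -0.13 (14 genes, 0.831), with S100b at -1.33 and Snap25 below the floor in the Wnt3A arrays. Skeletal muscle markers had a median of -0.08 and a mean of 0.10 (17 genes, 0.978), with Ckm at 1.54 and Acta1 moving from a mean of 1.63 to 3.13.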

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

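All 3 tests in this part were chosen after the mismatch between the table and the scanner files had been seen, while the marker lists were written before. Beyond the factor of the floor, which sets the probes tested and the lower bounds, the scanner files were not used in the main comparison. They held signal from macrophage and myeloid markers, in arrays of both groups but unequally. The median percentile of these 23 genes within an array was 76.6 at the lowest (Wnt3A replicate 1) and 95.3 at the highest (Wnt3A replicate 2), against 49.3 to 51.1 in the table. Laptm5 lay at percentiles 91.9 to 99.2 in the scanner files and 20.1 to 27.4 in the table, and Coro1a at 97.8 to 99.6 and 53.8 to 74.0. In Wnt3A replicate 1 other markers were lower, with Ptprc at 37.4 and Tyrobp at 56.6, against 84.4 to 95.1 and 94.2 to 99.6 in the other scanner files. Mpo was not lower there, at 99.8 against 94.9 to 99.1. The rise was not particular to myeloid markers, since endothelial markers lay at 55.3 to 73.6 in the scanner files and 32.8 to 43.3 in the table, and lymphoid and erythroid progenitor markers at 53.5 to 70.6 and 37.9 to 43.2. Sparc, a matrix gene, went the other way and lay at percentiles 46.6 to 92.0 in the scanner files and 98.7 to 99.5 in the table. The design gives no group that would account for this, and no biological explanation was tested.

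The values argue against a pair of explanations. Had the table been another normalization of the same scans, the ranks of bright spots would have been nearly the same in both. Over the 17653 spots well above background on all 4 scanner arrays, the highest rank correlation of a table column with the scanner file of its own sample was 0.780. Had the table's values been attached to the wrong probes, repeat spots of a probe would not match. The lowest correlation between the first 2 spots of a probe in any table column was 0.988.

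The explanation left open, that the scanner files hold other arrays than the table, may account for the mismatch. After each spot's mean over the 4 arrays of its source was taken off, the highest correlation of a table column with the scanner file of its own sample was 0.0491, over the spots well above background on all 4 scanner arrays. Noise in the scanner files that hides the differences between arrays would lower this value too. Rank correlations without this step decide nothing here, because all 4 table columns were closest to the file of Control replicate 2 (0.826 to 0.845) and to each other (0.924 to 0.954). Which of the sources holds the arrays that the labels describe cannot be decided from these values. The table has the higher matrix genes and lower myeloid markers, but this was not used as a test.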

How the results depend on the processing

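The quantile normalization of the table, the table without further scaling, the floor 2 times as high and the use of scanner values as an alternative were added after the data were seen. Against 92 genes that rose and 55 that fell, the 3 other scalings of the table gave 88 to 93 and 54 to 58. Dim values set to the floor gave 67 and 53. A 2-fold limit beside the adjusted p, fixed in advance, gave 92 and 55. It could remove no call, since the smallest called changes were 3.25 for rises and 3.10 for falls (log2). Without a filter 20 rose and 15 fell, and with probes above the floor on all 4 arrays 21 and 13. The counts were 118 and 84 with a floor 2 times as high, 126 and 107 with trend and robust settings, and 130 and 96 with the mean of a gene's probes. By fold alone with separated arrays they were 1960 and 1918. With the replicate block, limma called 0 and 0 genes, with 2737 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0978. The fit with a block recovered 70.4% of simulated changes of 4 (log2), a share that may be overstated. The replicate numbers paired nothing, since the differences between replicates correlated at 0.0124 across the groups. Leaving out each array gave 0 to 0 genes in both directions, where the lone array of a group is assumed to vary like the other group. A fit without 1 Control array recovered 2% of simulated changes of 4 and 68.8% of changes of 6. Where settings changed these results, the cause was not tested. Of 45 named genes past the threshold, 22 stayed without a filter, 19 with the stricter filter, 0 with the replicate block and 0 in the scanner values. The stricter filter left 70 of the 147 called genes measured and the scanner values 75. Named genes not measured count here as not staying, and 9 measured ones lost the call with the stricter filter.

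Higher lists stayed at 3 and lower lists at 3 or 4, except 6 higher with the mean of a gene's probes, 2 lower without a filter, 4 higher and 2 lower in fry, 0 and 0 with an estimated correlation, and 2 to 5 lower without an array. The replicate block ended the call of glycolysis and hypoxia genes (0.109). The scanner values gave 0 genes that rose and 2 that fell (480 unadjusted), and 0 and 0 lists. With normexp they gave 0 and 0 genes (220 unadjusted), 3 higher lists and 0 lower. With quantile normalization, and with both, they gave 0 and 0 genes (517 and 319 unadjusted) and 0 and 0 lists. The lowest r within groups minus the highest between was 0.0453 in the table and -0.131, -0.163, -0.172 and -0.156 in these 4 scanner settings. The Wnt3a probe was above the floor on 1 array, on 0 with a floor 2 times as high, and on 2 in the scanner values.

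In the table, reversed medians belonged to lists that were not called. Growth factors and IGF binding proteins had -0.00017 with quantile normalization, -0.0013 with the median of bright probes, -0.0054 without further scaling, -0.071 with the stricter filter and -0.12 with the mean of probes. Housekeeping genes had 0.038 with quantile normalization. Secreted Wnt antagonists had -0.066 without a filter, -0.12 with the stricter filter and -0.10 with the higher floor. Without a filter epithelial markers had 0.014 and neural markers -0.030, and with the mean of probes neural markers had -0.012 and collagens -0.0054. BMP and TGF-beta genes had 0.013 with the stricter filter, and myeloid markers 0.0059 with the higher floor. Leaving out each array gave medians of -0.083 to 0.29 for Wnt ligands, -0.33 to 0.10 for chondrocyte genes, -0.0087 to 0.047 for collagens, -0.091 to 0.041 for BMP and TGF-beta, -0.23 to 0.12 for growth factors, -0.32 to 0.30 for cell cycle and -0.031 to 0.42 for smooth muscle. The ranges were -0.042 to 0.29 for guidance genes, -0.24 to 0.29 for myeloid, -0.39 to 0.046 for lymphoid, -0.25 to 0.22 for epithelial, -0.089 to 0.047 for neural and -0.17 to 0.012 for skeletal muscle markers, and -1.23 to 0.084 for Tfrc.

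The scanner file of Control replicate 1 was faint, with a median intensity of 7.32 against 95.0 to 178 in the other files. How far the reversals below rest on it was not tested. In the scanner values 17 list medians were reversed. They were -0.49 for Wnt targets, -0.17 for Wnt ligands, -0.34 for Wnt receptors, -0.27 for secreted antagonists, -0.078 for osteoblast genes, -0.64 for proteoglycans, -0.40 for collagens, -0.41 for matrix proteases and -0.28 for growth factors. The others were -0.27 for p53 targets, 0.64 for glycolysis, 0.26 for cholesterol synthesis, -0.25 for cadherins, -0.38 for guidance genes, 0.38 for housekeeping genes, 0.094 for myeloid and -0.62 for neural markers. Of the named genes, 36 were reversed there. Those positive in the scanner values were Aldh3a1 (1.34), Ccl9 (2.31), Cd36 (0.37), Cd68 (0.19), Cdt1 (1.44), Gstt1 (1.36), Idi1 (0.36), Il7r (1.78), Meg3 (0.48), Mgst2 (0.51), Pfkl (2.13), Plxnd1 (1.63), Psmb8 (0.98), Sdha (1.26) and Sox18 (0.97). Those negative were Acta1 (-1.91), Ckm (-1.61), Cldn7 (-0.32), Col11a1 (-0.95), Ctnnb1 (-0.35), Dvl3 (-0.77), Eda2r (-0.27), Fgfr2 (-2.04), Fmod (-1.15), Hoxb9 (-0.57), Ifit2 (-0.34), Igfbp3 (-0.11), Igfbp5 (-0.24), Lef1 (-0.47), Ncam1 (-0.080), Nid2 (-0.24), Pdzrn3 (-0.12), Plagl1 (-0.35), Pth1r (-0.27), Robo2 (-0.49) and Vwf (-0.64). A slide block was not run, since the slides behind the table are not known. Genes whose lower group lay under the floor rest on dim signal, and a fold against them is bounded by it.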

Other observations

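The tests of chromosome medians and of the median of Y-linked probes were set before their results were seen. The Xist test, the count of lower Y-linked probes and the test of a lost Y chromosome were chosen afterwards. Only 3 splits of 4 arrays into 2 and 2 exist, too few for a share under 0.05. The real one called 147 genes in limma and the highest of the other 2 called 0. Probes had been kept by the real groups in all 3 splits, which favours the real one, so these counts decide nothing.

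Some Y-linked genes were lower in both Wnt3A arrays. No Wnt3A array was above the floor for Uty (at least 13.2-fold lower, adjusted p 0.0279), the brighter Ddx3y probe (at least 15.5-fold, 0.0319) or Eif2s3y (at least 18.6-fold, 0.0452), chosen here after their values were seen. Kdm5d changed by -1.86 (0.157). The others, Zfy1, Zfy2, Sry and an unnamed transcript, changed by -0.13 to 1.24, and none passed. Female cells in the Wnt3A samples would need a rise of Xist, and its change was -0.21 ± 0.32 (SE). The Xist probe was above the floor on both Control arrays too, where the Y-linked genes had signal. Whether it marks female cells here is therefore not known, and the lack of a rise does not decide against them. That dim probes fell together stays open. The median of the 11 Y-linked probes was -0.13, and 31.95% of 10000 random sets of like level lay as low, but the members went both ways. By the count chosen afterwards, 5 of the 11 were at least 2-fold lower, which 0.81% of random sets reached. Both Ddx3y probes were among those 5, while the random sets drew probes independently, so this share may be too small. Loss of the Y chromosome from the Wnt3A cells may explain the fallen genes. The 6 Y-linked probes that stayed above the floor on both Wnt3A arrays were those of Zfy1, Zfy2, Sry and the unnamed transcript. Whether those probes match the Y chromosome alone, or measure expression in these cells, is not known, so they do not decide against such a loss. These explanations cannot be told apart with the probes at hand.

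Genes of chromosome 1 were shifted upwards as a whole. Their median change lay 0.22 above that of the other chromosomes (log2, 1319 genes, 63.5% of them higher), with 0.0001 of random gene sets as far, the smallest share 10000 sets can give. All 10 windows of 20 Mb along the chromosome had medians above 0, from 0.09 to 0.43. Chromosome 5 lay 0.13 above the others, chromosome 2 at -0.08 and chromosome 17 at -0.09, all outside the random sets but under the 0.2 set in advance. Over genes brighter than the median, chromosome 5 lay 0.202 above the others and chromosome 1 lay 0.256 above. Random gene sets measure the spread between genes and not between arrays. Chromosome medians of Control replicate 2 minus replicate 1 ran from -0.14 to -0.06. The values argue against GC content of the probes as the source, since the shift of chromosome 1 was 0.23 after a trend on GC content and level was removed. A difference in chromosome copy number between the Control and Wnt3A cells may explain the shift, and it stays a hypothesis, since no DNA was measured. If it holds, the groups differed by more than the inserted gene, and changes of single genes cannot be assigned to Wnt3A from these arrays alone.

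Further genes were chosen after their values were seen. In the imprinted region of chromosome 12, Meg3 and Rian passed, while Mirg (-4.59, adjusted p 0.114), Dio3 (-4.92, 0.0528) and Dlk1 (0.39) did not. No Wnt3A array was above the floor for Mirg, so its change was taken without the floor and rests on dim signal. Among other imprinted genes, Peg10 fell by 4.85 (0.0328), Plagl1 rose by 6.23, and H19 (0.05), Sgce (-0.36), Cdkn1c (-0.23) and Zim1 (1.48) did not pass. No list of imprinted genes was fixed or tested. Of 31 Hox genes tested, 2 passed, Hoxb8 (5.29, 0.0423) and Hoxb9 (6.29, 0.0226), both higher.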
